A study of Mus musculus with 6 samples.

How the data were processed

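RNA labelled as from mouse cranial bone was measured by poly(A)-selected RNA sequencing in 6 libraries, 3 labelled control (0 µM metformin) and 3 labelled as treated at 500 µM. The labels describe paired reads of 150 bp and a cranial defect model with a defect diameter of 5 mm. The second group is the metformin scaffold group: metformin (a biguanide used against type 2 diabetes) carried by a composite of α-hemihydrate calcium sulfate and nano-hydroxyapatite, a mineral bone filler. The labels do not say whether the control received no material or the composite without drug, nor whether RNA came from tissue or cultured cells, nor whether the 3 replicates of a group were separate animals or cultures. The p-values therefore measure only the spread between these samples, which may be technical.

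The submitters' processing notes name bcl2fastq 2.20, fastp, HISAT2, StringTie, DESeq2 and edgeR without their roles, and the genome build is not given in the sources used here. The deposited table holds 28802 genes with an FPKM value and an estimated count per library, both made by the authors before deposit. FPKM is normalised by the authors for gene length and library size. The deposited estimated counts are not whole reads: low values pile up at 4, 8 and 12, which make up 31.8% to 33.6% of the values from 1 to 12 in each library, so 1 read pair was taken to be worth about 4 counts. Over 11218 genes with more than 200 counts in every library, the ratio of count to FPKM departed from a single factor per library by a median of 0.025%, after each gene's own length was allowed for. Total counts were between 63174927 and 70955139 per library, with about 1 read pair for every 4 counts. No column was left without a sample. In all, 99.7% of the gene identifiers were found in GENCODE M21 (GRCm38), and 90.6% of those had identical start and end. Coordinates are those of the table and are printed only for genes whose coordinates match that annotation.

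The plan named limma on FPKM, and edgeR if the table also held counts. It does, so the condition set before the data were examined applied. Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): genes were kept by filterByExpr with its minimum count of 10, scaled by TMM, and tested two-sided with the quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Fold changes are metformin scaffold over control. Where all 3 libraries of a group were at 0, a bound was computed against a floor of 3 read pairs over the group, at 4 counts each. Where a group held 1 to 3 read pairs, the ratio was given with its 95% exact binomial (Clopper-Pearson) interval. Reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only.

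In all, 51 gene lists were fixed from textbook knowledge before the data were examined. The 47 with at least 5 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01. Each was tested again with an estimated correlation and with fry, whose directional p asks whether the genes of a list move, on balance, one way. With an estimated correlation, camera also uses only the few residual degrees of freedom of the 6 libraries, which raises its p-values by itself. A symbol shared by several gene identifiers entered a list once, as the identifier with the highest count. GO and KEGG terms written in the authors' table, with 10 to 500 tested members, were tested for enrichment with a one-sided Fisher's exact test over the 13214 tested genes that carried a GO term (5298 for KEGG). Principal components and correlations used log2(FPKM + 1) over 11834 genes with a mean FPKM of at least 1.

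The genes named follow a rule fixed before the data were examined. They are the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, without predicted or unnamed genes; the 3 tested members with the smallest p, in the list's direction, of each list that passed; and 15 genes fixed in advance for bone and for metformin. Of the last, 2 are not analysed here. A gene outside the rule is said to have been chosen after its values were seen.

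Both tests were checked on simulated counts drawn from the means and library sizes of these samples. Changes were planted only in genes above a minimum mean count, so the shares found do not hold for the lowest transcripts. The shares for limma are of the planted genes that its filter kept. For control against metformin scaffold, simulated with 16942 genes in the run, edgeR recovered 26% of the genes changed 1.25-fold, 84% of those changed 1.5-fold, 90% of those changed 2-fold and 98% of those changed 4-fold, and 6.29% of its calls were false. With limma and 12852 genes, these shares were 26.7%, 77.1%, 85.4% and 100%, and 8.11% of the calls were false. A planted list of raised genes passed camera, and 0 of the random lists did. The simulated genes were drawn independently, so the check cannot show how often lists of genes that vary together pass falsely. In the real data the estimated inter-gene correlation was 0.543 for the mitosis list.

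Replicate pairs were compared before averaging. The chi-square of read pairs per degree of freedom was between 3.45 and 9.08 within groups, so no 2 libraries agreed within counting noise. The alternatives were other pseudocounts, filters, scalings and sample weights, a fold change threshold, robust moderation, each library left out in turn, the replicate number as a block, DESeq2 1.42.0, and limma on FPKM. Added after the data were seen were counts divided by 4, upper quartile scaling and library totals alone in edgeR, a library size without mitochondrial genes and their copies, and removal of a trend with GC content and length. Lists of kidney, heart, liver, neuron and blood transcripts were also written after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.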

Results

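Messenger RNA labelled as from mouse cranial bone was sequenced in 6 libraries, 3 from the control group (0 µM metformin) and 3 from the metformin scaffold group (500 µM metformin in a composite of α-hemihydrate calcium sulfate and nano-hydroxyapatite). The total estimated counts were 63174927, 70318881 and 68258311 in control replicates 1 to 3, and 70955139, 69932030 and 64683314 in scaffold replicates 1 to 3. Between 22240 and 23043 genes had a count above 0. Mitochondrially encoded transcripts took 6.4%, 7.16% and 7.06% of the counts in the control libraries and 6.96%, 7.74% and 8.58% in the scaffold libraries. The comparison asks which genes differ between the metformin scaffold and control. The labels give cranial bone as the source and do not say whether RNA was taken from tissue directly or from cultured cells. In control, Ptprc (leukocytes) stood at 0.00665 ± 0.00517 FPKM, Hba-a1 (red cells) at 0.0999 ± 0.0996, Pecam1 (endothelium) at 0.0961 ± 0.0197 and Lyz2 (macrophages and neutrophils) at 8.77 ± 1.48 (SD, n = 3). Over all libraries, the erythroid list had a median of 0.0417 FPKM, neutrophils 0.0298, B cells 0.0540, and macrophages and monocytes 0.0654. These levels argue against RNA of whole bone with its blood and marrow, while Lyz2 goes the other way. They do not show whether the cells were cultured.

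Osteoblast genes were highly expressed in both groups. The osteoblast and bone matrix list had a median level of 19.4 FPKM, with 20 of its 24 measured genes at 1 FPKM or more, and Col1a1 (the main chain of type I collagen) stood at 2173 ± 254 FPKM in control and 2163 ± 128 in scaffold (SD, n = 3 each, as for all group values). Osteocyte genes had a median of 10.7 FPKM, with 7 of 11 at 1 FPKM or more. The highest of them was Cd44, at a mean of 47.3 FPKM over all libraries. The osteocyte genes Sost and Fgf23 were near the floor. Sost stood at 0.0205 ± 0.0209 FPKM in control and 0.0245 ± 0.00238 in scaffold, and Fgf23 at 0.00929 ± 0.0161 and 0. Genes of T and NK cells had a median of 0.00629 FPKM and those of endothelium a median of 0.0873 FPKM. The summed FPKM of the osteoblast list was 8094 ± 622 in control and 9414 ± 107 in scaffold, of which Ibsp made up 1266 ± 55.3 and 2116 ± 119. The adipocyte list summed to 3.84 ± 0.0983 and 5.73 ± 0.629 FPKM, of which Car3 made up 0.509 ± 0.123 and 2.26 ± 0.555, and the neutrophil list to 4.11 ± 0.779 and 2.40 ± 0.364 FPKM, of which Lcn2 made up 3.62 ± 0.507 and 2.12 ± 0.216. Most other members of both lists were under 1 FPKM. The erythroid list summed to 28.2 ± 1.21 FPKM in control and 17.2 ± 0.909 in scaffold. Of its 13 measured genes, 1 reached 1 FPKM, the transferrin receptor gene Tfrc. Lcn2, Tfrc, Cd44, Sost, Fgf23, Ptprc, Hba-a1, Pecam1 and Lyz2 were chosen after their values were seen.

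With the metformin scaffold, 25 of 25 tested genes of mitosis rose, 19 of 23 of cholesterol synthesis, 13 of 20 of glycolysis, 14 of 22 of bone matrix and 8 of 19 hypoxia targets, with list medians between 1.21-fold (hypoxia) and 1.47-fold (mitosis). These 5 lists passed the set test at its preset correlation; with an estimated correlation cholesterol synthesis and hypoxia passed (adjusted p = 0.0139 each), and mitosis, glycolysis and bone matrix did not (adjusted p = 0.0596 each). The mineralisation genes Dmp1 and Bglap rose 4.35-fold and 3.79-fold, and the hypoxia marker Car9 rose 3.61-fold. Among the largest falls were Kap and Slc34a1, transcripts best known from the kidney, at low levels. Of 17375 genes tested with edgeR (Benjamini-Hochberg adjusted p under 0.05), 496 were higher and 253 lower, with a median fold of 1.38 and 0.773. Changes of at least 2-fold were seen in 50 higher and 24 lower genes. The 2 groups did not overlap in 746 of the 749 genes that passed, and in 4163 of all tested genes (24%, where chance gives 10%). For every gene named here as having passed, each of the 3 scaffold libraries lay on the same side of all 3 control libraries. The naming rule required this of the largest rises and falls, and nearly all genes that passed have it, so it adds no separate support. Of the genes that passed, 66.2% were higher, against 53% (429 higher, 380 lower) when libraries were scaled by their totals alone and 55.9% (328 higher, 259 lower) with limma on FPKM. At a mean FPKM of at least 5 the share was 54.9% (311 higher, 256 lower) with edgeR, and with sample weights in limma the majority turned, with 46.4% higher (518 higher, 599 lower). The counts fell to 304 higher and 111 lower without control replicate 2, 333 and 127 without control replicate 3, 304 and 117 without scaffold replicate 2, and 234 and 89 without scaffold replicate 3.

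**Figure D1:**
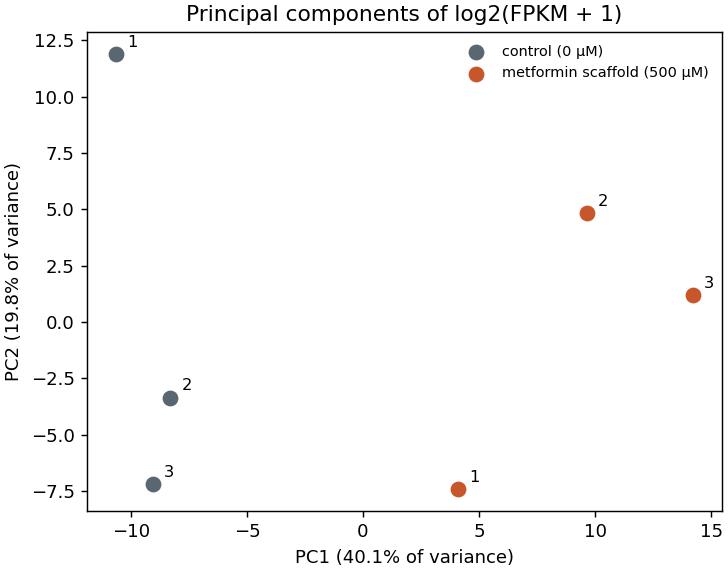
Each point is 1 of the 6 libraries, placed by its scores on the first (40.1% of variance) and second (19.8%) principal components of log2(FPKM + 1) over 11834 genes. The control libraries lie between -10.6 and -8.29 on the first component and the scaffold libraries between 4.10 and 14.2, while control replicate 1 stands apart on the second component at 11.9.

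Control and scaffold libraries separated on the first principal component, which held 40.1% of the variance. Control replicate 1 stood at 11.9 on the second component, against -3.36 and -7.20 for the other control libraries. Pearson correlations of log2(FPKM + 1) across genes, which are not independent replicates, were 0.991 to 0.994 within groups and 0.985 to 0.990 between them. Among the 47 gene lists tested with camera, 16 passed, 14 higher and 2 lower. With an estimated inter-gene correlation, 3 passed: cholesterol synthesis, hypoxia targets and immediate early genes. This setting also lowers the degrees of freedom, so a lost call does not by itself show that the genes of a list vary together. The MAPK/ERK feedback list lost its call (camera adjusted p = 0.0596) at an estimated correlation of -0.0230. Of the 16, 12 also passed fry, and 4 did not: collagen and extracellular matrix (fry adjusted p = 0.154), mitochondrially encoded genes (0.255), ribosomal proteins (0.496) and IGF and insulin signalling (0.0865).

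**Figure D2:**
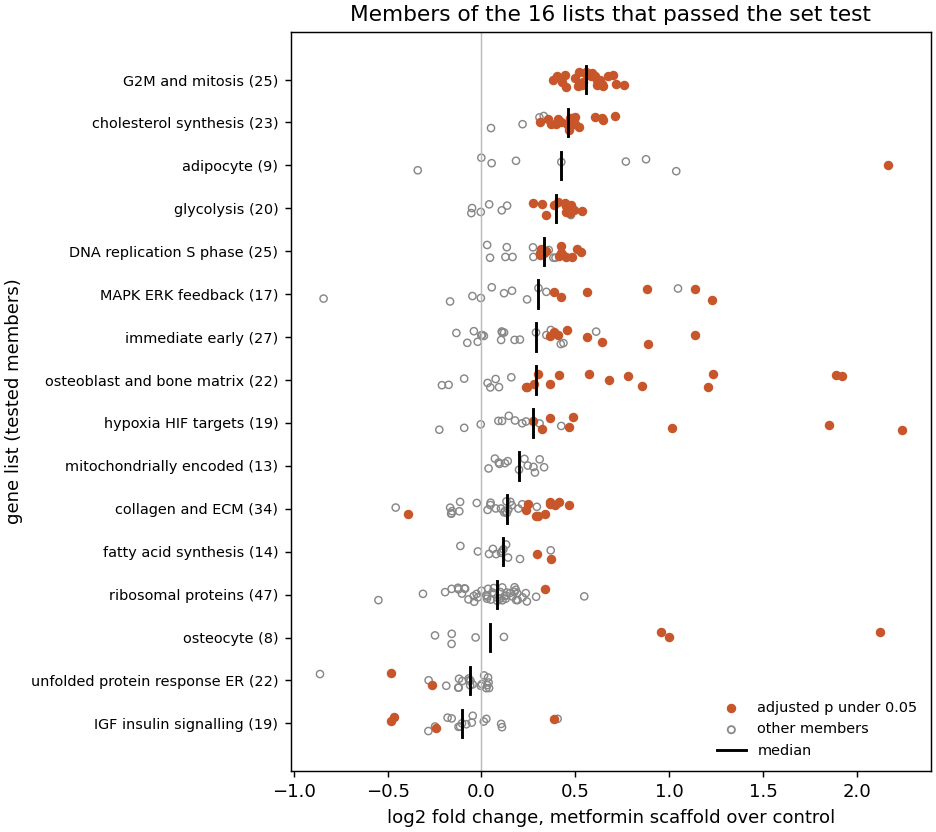
Each point is the log2 fold change (metformin scaffold over control) of a tested member of the 16 gene lists that passed the set test, filled where its edgeR adjusted p was under 0.05, with a black bar at the list's median and the number of tested members in parentheses. The medians run from -0.10 for IGF and insulin signalling to 0.56 for mitosis, where all 25 points are filled.

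The mitosis and DNA replication lists passed the set test in the higher direction. All 25 genes of the G2/M and mitosis list rose, with a median log2 fold change of 0.56, and all 25 also passed when adjusted over the list alone. Tpx2, a spindle assembly factor (ENSMUSG00000027469, chromosome 2, 152847964 to 152895321, GRCm38), went from 47.8 ± 1.85 to 72.6 ± 4.56 CPM (counts scaled to library size), a log2 fold change of 0.60 ± 0.06 (SE; edgeR adjusted p = 0.000633). Top2a, the topoisomerase of dividing cells (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189), went from 136 ± 4.44 to 194 ± 7.43 CPM (log2 fold change 0.52 ± 0.05, edgeR adjusted p = 0.000676). Ccnb2, cyclin B2, rose by 0.76 ± 0.09 on the log2 scale (edgeR adjusted p = 0.00125). In the DNA replication list 13 of 25 genes rose, 19 when adjusted over the list alone, with a median of 0.33; the replicative helicase genes Mcm5 (0.53 ± 0.07, edgeR adjusted p = 0.00178) and Mcm2 (0.51 ± 0.07, edgeR adjusted p = 0.00266) and the maintenance methylation cofactor Uhrf1 (0.48 ± 0.07, edgeR adjusted p = 0.00352) were among them. The camera adjusted p was 4.35e-60 for mitosis and 5.45e-18 for DNA replication, and with an estimated correlation the adjusted p was 0.0596 and 0.0727. The DNA replication count was 8, 7 and 8 without control replicates 1, 2 and 3, and 4 without scaffold replicate 3. By Fisher's exact test, 72 of the 417 tested genes annotated to the cell cycle were among the higher genes (adjusted p = 4.89e-28 over 1957 GO terms).

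Several genes of bone matrix and mineralisation were higher, while Col1a1 and Spp1 did not pass the test. In the osteoblast and bone matrix list 14 of 22 tested genes rose and the other 8 did not pass (14 higher and 1 lower when adjusted over the list alone), with a median log2 fold change of 0.29 (camera adjusted p = 1.79e-20; adjusted p = 0.0596 with an estimated correlation). Ibsp, bone sialoprotein (ENSMUSG00000029306, chromosome 5, 104299171 to 104311469), went from 2885 ± 105 to 4957 ± 301 CPM, a log2 fold change of 0.78 ± 0.06 (edgeR adjusted p = 0.000118). The osteocalcin genes Bglap (ENSMUSG00000074483, chromosome 3, 88383501 to 88384464) and Bglap2 (ENSMUSG00000074486, chromosome 3, 88377736 to 88378699) rose by 1.92 ± 0.18 (edgeR adjusted p = 0.000459) and 1.89 ± 0.17 (edgeR adjusted p = 0.000409). They are near-identical copies, so the split of reads between them is uncertain. With the counts of the 3 osteocalcin copies added, the level went from 9.28 to 34.5 CPM (log2 fold change 1.90 ± 0.14, edgeR adjusted p = 8.81e-05). Alpl, tissue non-specific alkaline phosphatase (ENSMUSG00000028766, chromosome 4, 137741733 to 137796384), rose from 23 ± 0.806 to 34.2 ± 3.33 CPM (0.57 ± 0.08, edgeR adjusted p = 0.00276). Of the osteoblast transcription factors, Sp7 rose by 0.24 ± 0.06 (edgeR adjusted p = 0.0370), and Runx2 stood at -0.17 ± 0.07 (edgeR adjusted p = 0.179). Col1a1 stood at 0.03 ± 0.08 (edgeR adjusted p = 0.877) and Spp1, osteopontin, at 0.09 ± 0.07 (edgeR adjusted p = 0.562). The osteoblast count was 9 without control replicate 2, 8 without control replicate 3, 9 without scaffold replicate 2 and 7 without scaffold replicate 3, and Sp7 lost its call without each of these 4 libraries (adjusted p from 0.129 to 0.160).

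Of 8 osteocyte genes tested, 3 mineralisation genes, Dmp1, Mepe and Phex, rose and the other 5 did not pass. When adjusted over the list alone, 3 were higher and 2 lower. Dmp1, dentin matrix protein 1 (ENSMUSG00000029307, chromosome 5, 104202613 to 104214102), went from 3.05 ± 0.219 to 13.3 ± 2.95 CPM (log2 fold change 2.12 ± 0.17, edgeR adjusted p = 0.000118). Mepe, its neighbour in the same gene cluster (ENSMUSG00000053863, chromosome 5, 104325329 to 104338611), rose by 1.00 ± 0.09 (edgeR adjusted p = 0.000459). Phex, an endopeptidase of phosphate control, rose by 0.96 ± 0.16 (edgeR adjusted p = 0.00641). The list passed camera in the higher direction (adjusted p = 0.00104; adjusted p = 0.323 with an estimated correlation), with a mean log2 fold change of 0.45 and a median of 0.04. It lost its call under every alternative with limma on FPKM. The limma median was -0.07 at a pseudocount of 1 (adjusted p = 0.620) and -0.13 at a mean of at least 5 FPKM (adjusted p = 0.831). It also lost its call with edgeR at a mean of at least 5 FPKM (median -0.11, adjusted p = 0.966). Tnfrsf11b, osteoprotegerin, the decoy receptor that restrains osteoclast formation (ENSMUSG00000063727, chromosome 15, 54250619 to 54278484), rose from 44.8 ± 2.23 to 66.3 ± 4.85 CPM (0.57 ± 0.07, edgeR adjusted p = 0.00137).

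The hypoxia target and glycolysis lists passed the set test in the higher direction. Car9, the carbonic anhydrase induced through hypoxia-inducible factor (ENSMUSG00000028463, chromosome 4, 43506966 to 43513729), went from 7.06 ± 0.507 to 25.5 ± 1.29 CPM, a log2 fold change of 1.85 ± 0.09 (edgeR adjusted p = 2.12e-06). Ankrd37 rose by 2.24 ± 0.18 (edgeR adjusted p = 0.000141); it overlaps Ufsp2 on the opposite strand, and strand use in counting is not given in the sources used here. Bhlhe40, a transcriptional repressor, rose by 1.02 ± 0.08 (edgeR adjusted p = 0.000141). Of 19 hypoxia targets tested, 8 rose and the other 11 did not pass, with 11 higher when adjusted over the list alone, with a median of 0.28 (camera adjusted p = 1.02e-21; adjusted p = 0.0139 with an estimated correlation). Of 20 glycolysis genes, 13 rose and the other 7 did not pass, with 13 higher also when adjusted over the list alone, with a median of 0.40 (camera adjusted p = 2.93e-19; adjusted p = 0.0596 with an estimated correlation). Pgk1, phosphoglycerate kinase (ENSMUSG00000062070, chromosome X, 106187100 to 106203699), went from 233 ± 19 to 337 ± 16 CPM (0.53 ± 0.07, edgeR adjusted p = 0.00178); it has processed copies that may share its reads. Pfkl, liver-type phosphofructokinase, rose by 0.45 ± 0.06 (edgeR adjusted p = 0.00178), as did the pyruvate kinase gene Pkm (0.45 ± 0.06, edgeR adjusted p = 0.00224). Vegfa, the angiogenic hypoxia target, stood at 0.18 ± 0.06 (edgeR adjusted p = 0.125).

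Most cholesterol synthesis genes rose in the scaffold libraries. Of 23 tested, 19 rose and the other 4 did not pass, with 21 higher when adjusted over the list alone, with a median log2 fold change of 0.46 (camera adjusted p = 7.51e-49; adjusted p = 0.0139 with an estimated correlation). Fdps, farnesyl diphosphate synthase (ENSMUSG00000059743, chromosome 3, 89093588 to 89101959), went from 59.6 ± 1.02 to 97.7 ± 1.11 CPM, a log2 fold change of 0.71 ± 0.05 (edgeR adjusted p = 4.50e-05). Idi1, isopentenyl diphosphate isomerase, rose by 0.64 ± 0.07 (edgeR adjusted p = 0.000633), and Msmo1, a sterol demethylation enzyme, by 0.61 ± 0.06 (edgeR adjusted p = 0.000517). In the fatty acid synthesis list 2 of 14 genes rose, 3 when adjusted over the list alone: Scd1, stearoyl-CoA desaturase (0.37 ± 0.05, edgeR adjusted p = 0.00223), and Fads2, a fatty acid desaturase (0.29 ± 0.06, edgeR adjusted p = 0.0119), passed over all genes. Acsl3 stood at 0.21 ± 0.07 (edgeR adjusted p = 0.122) and overlaps Utp14b. The list had a median of 0.11 (camera adjusted p = 0.00168; adjusted p = 0.439 with an estimated correlation). Fads2 lost its call without control replicates 2 and 3 and scaffold replicates 2 and 3 (adjusted p from 0.0553 to 0.0716), which left 1 gene of the list.

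Some immediate early genes and feedback genes of the MAPK/ERK pathway rose. The lists share members, among them Dusp6 and Egr1, so their set tests are not independent. Of 27 immediate early genes, 8 rose and the other 19 did not pass, with 13 higher when adjusted over the list alone, with a median of 0.29 (camera adjusted p = 4.09e-08; adjusted p = 0.0445 with an estimated correlation). Of 17 MAPK/ERK feedback genes, 6 rose and the other 11 did not pass, with 9 higher when adjusted over the list alone, with a median of 0.30 (camera adjusted p = 3.01e-06; adjusted p = 0.0596 with an estimated correlation). Etv4, a transcription factor induced by ERK (ENSMUSG00000017724, chromosome 11, 101769742 to 101785371), rose from 2.94 ± 0.544 to 6.90 ± 0.644 CPM (1.23 ± 0.16, edgeR adjusted p = 0.00229). The ERK phosphatase gene Dusp6 rose by 0.57 ± 0.09 (edgeR adjusted p = 0.00450), Ier3 by 0.46 ± 0.07 (edgeR adjusted p = 0.00376) and the zinc finger gene Egr1 by 0.39 ± 0.07 (edgeR adjusted p = 0.00775). The immediate early count was 5 without control replicate 2, 5 without control replicate 3, 4 without scaffold replicate 2 and 3 without scaffold replicate 3.

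In 4 further lists that passed in the higher direction, under 1 in 3 of the tested genes rose with edgeR. In the collagen and extracellular matrix list 10 of 34 genes rose and 1 fell (14 and 1 when adjusted over the list alone and with DESeq2, 3 and 1 with limma; median 0.13, camera adjusted p = 1.71e-05, adjusted p = 0.501 with an estimated correlation). The prolyl hydroxylase genes P4ha1 (0.46 ± 0.06, edgeR adjusted p = 0.00142) and P4ha2 (0.37 ± 0.06, edgeR adjusted p = 0.00831), which modify collagen and are also known hypoxia targets, and the proteoglycan gene Vcan (0.41 ± 0.06, edgeR adjusted p = 0.00332) were among those that rose. That count of 10 was 3 without control replicate 2, control replicate 3 or scaffold replicate 3, and 4 without scaffold replicate 2. All 13 mitochondrially encoded genes had positive values, with a median of 0.20 (camera adjusted p = 0.000301; adjusted p = 0.589 with an estimated correlation, and 0.980 with quantile normalisation, under which the median was zero), but 0 passed over all genes with edgeR (7 higher at an unadjusted p under 0.05, 6 higher with DESeq2, 0 with limma) and 5 were higher when adjusted over the list alone. mt-Nd1 stood at 0.33 ± 0.09 (edgeR adjusted p = 0.0594), mt-Atp8, which overlaps mt-Atp6, at 0.31 ± 0.09 (edgeR adjusted p = 0.0725), and mt-Co2 at 0.29 ± 0.08 (edgeR adjusted p = 0.0844); nuclear copies may share their reads. Without scaffold replicate 1, 6 of the 13 passed. Of 47 ribosomal protein genes 1 rose and the other 46 did not pass with edgeR, with 5 higher when adjusted over the list alone. There were 13 higher at an unadjusted p under 0.05, 9 higher with DESeq2 and 0 with limma, and 5 higher with edgeR after a GC and length trend was removed. Their median was 0.08 (camera adjusted p = 0.00804; adjusted p = 0.813 with an estimated correlation), and -0.00124 with sample weights in limma. The gene that rose was Rpl35 (0.34 ± 0.08, edgeR adjusted p = 0.0460), which overlaps Arpc5l on the opposite strand and kept its call in 1 of 6 fits that left out a library, the one without scaffold replicate 1 (adjusted p from 0.0435 to 0.201). Rpl19 stood at 0.29 ± 0.08 (edgeR adjusted p = 0.0618) and Rps6 at 0.24 ± 0.06 (edgeR adjusted p = 0.0657). The ribosomal list lost its call without control replicate 1 (camera adjusted p = 0.566) and without scaffold replicate 1 (camera adjusted p = 0.968), where 3 genes were higher and 4 lower. The adipocyte list (median 0.43, camera adjusted p = 0.0156, adjusted p = 0.226 with an estimated correlation) had 1 of 9 genes that rose, 1 also when adjusted over the list alone: Car3, carbonic anhydrase 3, also a skeletal muscle enzyme, at 2.17 ± 0.22 (edgeR adjusted p = 0.000633). Fabp4 (0.77 ± 0.32, edgeR adjusted p = 0.226) and Lpl (0.88 ± 0.42, edgeR adjusted p = 0.306) did not pass, and 2 adipocyte genes passed without control replicate 1.

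The IGF and insulin signalling list and the unfolded protein response list passed the set test in the lower direction, with few genes called in each. Positive values were seen in 6 of 19 and 7 of 22 tested genes. At an unadjusted edgeR p under 0.05, 7 genes were lower and 1 higher in the first list, and 3 lower and 0 higher in the second. DESeq2 called 6 lower and 1 higher in the first, and 3 lower and 0 higher in the second. In the IGF and insulin signalling list 3 of 19 genes fell and 1 rose, 5 and 1 when adjusted over the list alone, with a median of -0.10 (camera adjusted p = 0.0138; adjusted p = 0.399 with an estimated correlation). Igfbp6, an IGF binding protein (ENSMUSG00000023046, chromosome 15, 102144362 to 102149511), went from 28.9 ± 1.08 to 20.7 ± 0.494 CPM (-0.48 ± 0.07, edgeR adjusted p = 0.00276). Pik3r1, a regulatory subunit of PI3-kinase, stood at -0.46 ± 0.07 (edgeR adjusted p = 0.00376) and the growth factor gene Igf1 at -0.24 ± 0.05 (edgeR adjusted p = 0.0286). The gene that rose was Igf2, the fetal growth factor (0.39 ± 0.07, edgeR adjusted p = 0.00716), named after its value was seen. Of 22 unfolded protein response genes 2 fell and the other 20 did not pass, with 2 lower also when adjusted over the list alone, with a median of -0.06 (camera adjusted p = 0.0158; adjusted p = 0.399 with an estimated correlation). They were the Hsp40 co-chaperone genes Dnajb9 (ENSMUSG00000014905, chromosome 12, 44205559 to 44210326; -0.48 ± 0.08, edgeR adjusted p = 0.00487) and Dnajc3 (-0.26 ± 0.05, edgeR adjusted p = 0.0194), while the chaperone gene Hspa5 stood at -0.19 ± 0.06 (edgeR adjusted p = 0.102). Without scaffold replicate 1 neither list passed (camera adjusted p = 0.102 and 0.0729). Igf1 lost its call without control replicates 1 and 2 and scaffold replicates 2 and 3 (adjusted p from 0.0585 to 0.151), and Dnajc3 without control replicates 2 and 3 and scaffold replicates 2 and 3 (adjusted p from 0.0893 to 0.106), which left 1 gene of its list.

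Lists of AMP-activated kinase and metformin transport, complex I, ATF4, BMP, Wnt and NF-κB genes did not pass camera. Cholesterol synthesis, glycolysis and IGF and insulin signalling, also tied to AMP-activated kinase or insulin action, passed at the preset correlation. Cholesterol synthesis and glycolysis passed in the higher direction, and IGF and insulin signalling in the lower. That they passed does not show a change in the activity of the kinase. With an estimated correlation cholesterol synthesis passed (camera adjusted p = 0.0139). Glycolysis (camera adjusted p = 0.0596) and IGF and insulin signalling (camera adjusted p = 0.399) then did not. Of 17 genes of AMP-activated kinase and metformin transport, 0 passed over all genes with edgeR, with 1 lower when adjusted over the list alone (median -0.03, camera adjusted p = 0.955). At an unadjusted p under 0.05 there were 4 higher and 3 lower, and DESeq2 and limma each called 1 lower. Prkaa1 and Prkaa2, the catalytic subunits of AMP-activated kinase, stood at -0.05 ± 0.06 (edgeR adjusted p = 0.676) and 0.12 ± 0.17 (edgeR adjusted p = 0.772). Of the 37 tested subunits of respiratory complex I, which metformin is known to inhibit, 0 passed with edgeR over all genes and 0 when adjusted over the list alone, with 4 lower at an unadjusted p under 0.05 and 0 called by DESeq2 or limma (median -0.07, camera adjusted p = 0.152). In the ATF4 and integrated stress response list 1 of 31 genes rose and 1 fell, 5 and 3 when adjusted over the list alone and with DESeq2, 0 and 3 with limma (camera adjusted p = 0.692). Atf4 stood at -0.02 ± 0.06 (edgeR adjusted p = 0.918) and Ddit3, which overlaps Mars1 on the opposite strand, at -0.01 ± 0.06 (edgeR adjusted p = 0.946). Of 15 BMP targets 1 rose and 1 fell, 2 and 1 when adjusted over the list alone (camera adjusted p = 0.460), and of 14 Wnt targets 2 rose and 1 fell, 3 and 2 when adjusted over the list alone (camera adjusted p = 0.152). In the NF-κB list 2 of 22 genes fell and the other 20 did not pass, with 3 lower when adjusted over the list alone; its median was 0.10 while camera pointed lower (adjusted p = 0.962). A p above the threshold does not show that these genes were unchanged, since the test found 26% of the smallest changes in simulated data. RNA levels also do not measure the activity of complex I or of AMP-activated kinase.

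**Figure D3:**
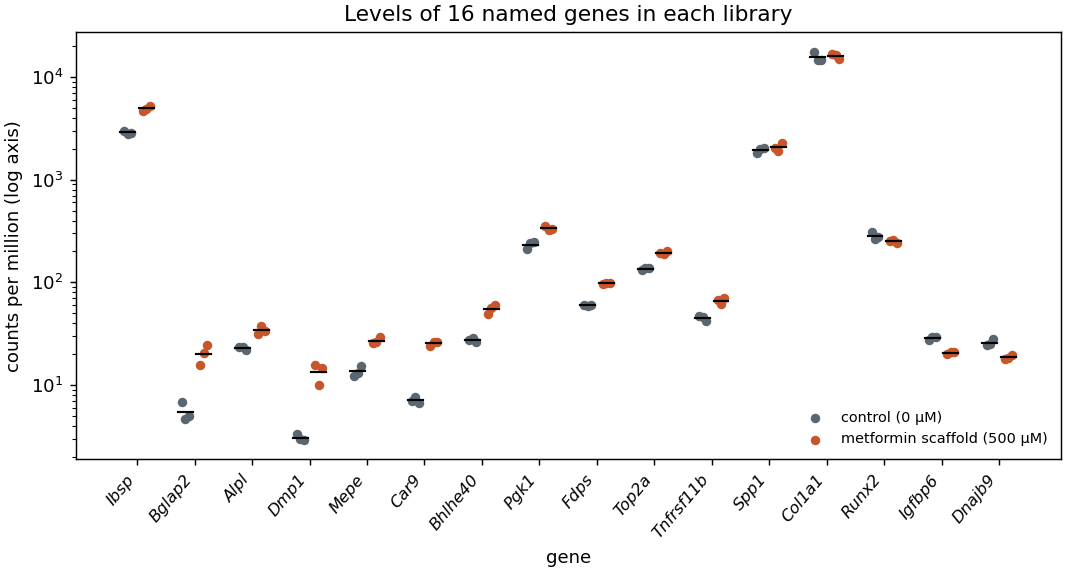
Level in CPM on a log axis for genes named in the text, with 1 point per library and a line at each group mean. For Car9 and Dmp1, the 3 scaffold libraries lie above the 3 control libraries, with means of 25.5 against 7.06 CPM and 13.3 against 3.05 CPM.

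The largest changes were mostly in transcripts of low level. Besides Dmp1, Ankrd37 and Car3, the largest rises included the cardiac muscle genes Actc1, Myh6 and Ckmt2. Actc1, cardiac actin, went from 0.182 ± 0.167 to 1.62 ± 0.335 CPM (log2 fold change 3.16 ± 0.51, edgeR adjusted p = 0.00525). Myh6, cardiac myosin heavy chain, went from 0.475 ± 0.728 to 5.14 ± 0.397 CPM (3.46 ± 0.81, edgeR adjusted p = 0.0375), with 84, 8 and 0 counts in control replicates 1, 2 and 3. Ckmt2, mitochondrial creatine kinase of muscle (edgeR adjusted p = 0.0468), had about 2 read pairs in control against 24 in scaffold, a ratio of 11.8 with a 95% exact binomial counting interval from 2.92 to 103. Slc9a4 (edgeR adjusted p = 0.0437) had about 2 against 16 read pairs, a ratio of 7.85 with an interval from 1.85 to 70.4. Prss35 rose by 2.45 ± 0.42 (edgeR adjusted p = 0.00756) and Aknad1 by 2.26 ± 0.54 (edgeR adjusted p = 0.0409). A Septin2 gene model (ENSMUSG00000116048, chromosome 1, 93478993 to 93509733) rose by 2.16 ± 0.22 (edgeR adjusted p = 0.000600), from 42.9 ± 13.5 to 192 ± 43.9 CPM; it overlaps the other Septin2 model (ENSMUSG00000026276), which stood at -0.74 ± 0.11 (edgeR adjusted p = 0.00296). The fitted log2 fold change rose without control replicate 1 to 6.45 for Myh6, 4.21 for Actc1, 4.34 for Slc9a4 and 3.10 for Prss35, and that of Myh6 was 2.87 without control replicate 3; Ckmt2 had a count of 0 in the control libraries other than replicate 1. Leaving out a library ended the call of Slc9a4 for each of the 6 libraries (adjusted p from 0.0573 to 0.172). Ckmt2 kept its call without control replicate 1 only (adjusted p = 0.0132, and up to 0.225 without scaffold replicate 3), and so did Aknad1 (adjusted p = 0.0401, and up to 0.167 without scaffold replicate 2). Myh6 lost its call without control replicate 2 and without scaffold replicate 1, 2 or 3 (adjusted p up to 0.129).

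Transcripts best known from the kidney made up much of the largest falls. Kap, kidney androgen regulated protein (ENSMUSG00000032758, chromosome 6, 133849851 to 133853762), went from 9.48 ± 0.717 to 2.56 ± 1.49 CPM (log2 fold change -1.88 ± 0.30, edgeR adjusted p = 0.00510). Slc34a1, the sodium-phosphate transporter of the renal tubule, stood at -1.20 ± 0.24 (edgeR adjusted p = 0.0153), Klk1, tissue kallikrein, at -2.04 ± 0.45 (edgeR adjusted p = 0.0281), and the fatty acid transport gene Slc27a2 at -1.48 ± 0.28 (edgeR adjusted p = 0.0129). In the 3 scaffold libraries, Slco1a6, an organic anion transporter gene (edgeR adjusted p = 0.00476), Pcdhgb1 (edgeR adjusted p = 0.00939) and Slc26a4, the pendrin gene (edgeR adjusted p = 0.0183), had a count of 0. Against a floor of 3 read pairs over the group they were at least 7.29-fold, 4.89-fold and 3.81-fold lower. Pcdhgb1 overlaps many models of the protocadherin gamma cluster, so its value is uncertain. Nat3 (-1.96 ± 0.32, edgeR adjusted p = 0.00525), Fam222a (-1.39 ± 0.26, edgeR adjusted p = 0.0109) and Cyp4b1 (-1.32 ± 0.28, edgeR adjusted p = 0.0216) also fell. Leaving out a library ended the call of Klk1 for each of the 6 libraries (adjusted p from 0.0530 to 0.134) and that of Slc26a4 and Cyp4b1 for control replicates 1 and 2 and scaffold replicates 2 and 3 (adjusted p up to 0.0978 and 0.0913). Calls were also lost for Slc34a1 without control replicate 3 (adjusted p = 0.0822) or scaffold replicate 3 (adjusted p = 0.0725), Slc27a2 without control replicate 1 (adjusted p = 0.0576) or scaffold replicate 3 (adjusted p = 0.0579), Fam222a without control replicate 3 (adjusted p = 0.0536) and Pcdhgb1 without control replicate 2 (adjusted p = 0.0526).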

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

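The alternatives with counts divided by 4, upper quartile scaling, library totals alone, a library size without mitochondrial genes, and removal of a GC and length trend were chosen after the data were seen; the others were planned. Of 482 results for the gene lists under 31 alternatives, 441 kept their direction and side of the threshold, 40 lost their call and 1 reversed: the osteocyte list had a median log2 fold change of -0.13 (adjusted p = 0.831) with limma on FPKM and a mean of at least 5. The osteocyte list passed under no alternative with limma on FPKM. Of the lost calls, 13 were of the osteocyte list and 6 of the ribosomal protein list. Cholesterol synthesis, hypoxia targets and immediate early genes passed under all 31. Of 57 named genes past the threshold, 41 passed in every fit that left out a library, and 14 in every alternative without a fold change threshold. Of 1971 gene results, 222 lost their call, in part under a fold change threshold, 25 gained one and 0 reversed. A change of sign counted as reversed only where the gene passed in at least 1 of the fits compared. Among genes that did not pass, signs did change: Col1a1 ran from -0.0154 to 0.127 and Prkaa2 from -0.0331 to 0.215. The counts of 496 higher and 253 lower genes ran from 234 to 610 and from 89 to 358 when a library was left out, with the lowest without scaffold replicate 3 and the highest without scaffold replicate 1, and the lists that passed from 15 to 20. Without scaffold replicate 3, which leaves fewer samples, 318 of the 749 genes passed again.

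Stricter criteria gave fewer genes by their construction: 50 higher and 24 lower at a log2 fold change of at least 1 with edgeR, 14 and 3 with limma on FPKM. Without a filter, with more genes tested, edgeR gave 317 higher and 115 lower and limma 38 and 29; with fewer genes tested, at a mean FPKM of at least 5, edgeR gave 311 higher and 256 lower and limma 236 and 233. For the others the cause was not tested. DESeq2 gave 890 higher and 540 lower, with an adjusted p left undefined for 3710 genes, and called 731 of the 749. Limma gave 328 higher and 259 lower at a pseudocount of 1, 326 and 258 at 0.1, and 323 and 255 at 5. There were 429 higher and 380 lower with library totals alone, 605 and 407 with the GC and length trend removed, 392 and 157 with median centring in limma and 518 and 599 with sample weights, which gave control replicate 1 a weight of 0.431 and scaffold replicate 1 a weight of 0.579. With an estimated inter-gene correlation 3 lists passed.

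The groups share replicate numbers, but libraries of the same number did not deviate together (correlations 0.0181, 0.0140 and 0.00189, where each would have to be over 0.1). With the replicate number as a block, edgeR gave 460 higher and 191 lower genes, 582 of them shared with the 749, and limma gave 134 and 65. At totals of 63174927 to 70955139 counts, about 4 to a read pair, and 3 libraries per group, 26% of the smallest simulated changes were found, and the transcripts with the largest folds rest on few read pairs.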

Other observations

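Genes in the next 2 paragraphs were chosen after their values were seen, as were the kidney, heart, liver, neuron and blood lists and all tests of explanations except the counts over other splits of the samples. Extracellular matrix genes moved both ways. The most significant gene outside the rule was H19, an imprinted fetal long non-coding RNA (chromosome 7, 142575529 to 142578143), which went from 5.92 ± 0.579 to 24.9 ± 0.506 FPKM (log2 fold change 2.11 ± 0.08, edgeR adjusted p = 2.78e-07; higher in 3 of 3 scaffold libraries than in every control library, as for each rise here). Its imprinted neighbour Igf2 rose by 0.39 ± 0.07 (edgeR adjusted p = 0.00716). Panx3, a channel gene of osteoblasts and hypertrophic chondrocytes, went from 17 ± 0.843 to 38.6 ± 3.74 FPKM (1.22 ± 0.07, edgeR adjusted p = 2.40e-05), and the matrix vesicle phosphatase gene Phospho1 from 6.0 ± 2.31 to 13.7 ± 1.63 FPKM (1.24 ± 0.20, edgeR adjusted p = 0.00555). Of 14 tested chondrocyte genes, 3 rose, all of cartilage matrix: Col2a1, type II collagen, went from 31.8 ± 2.26 to 56.4 ± 1.24 FPKM (0.87 ± 0.06, edgeR adjusted p = 5.04e-05), with Hapln1 at 0.83 ± 0.11 (edgeR adjusted p = 0.00178) and Col11a2 at 0.98 ± 0.13 (edgeR adjusted p = 0.00223). Cnmd, chondromodulin, stood at -0.60 ± 0.07 (edgeR adjusted p = 0.00142), and the chondrocyte list did not pass camera (adjusted p = 0.507).

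Transcripts of several secreted proteins were lower in each of the 3 scaffold libraries than in every control library, as for each fall here. Ogn, the proteoglycan osteoglycin, went from 448 ± 26.9 to 230 ± 7.19 FPKM (-0.92 ± 0.06, edgeR adjusted p = 4.45e-05). Mgp, matrix Gla protein, an inhibitor of calcification, went from 1247 ± 87.9 to 747 ± 125 FPKM (-0.70 ± 0.10, edgeR adjusted p = 0.00352), and Postn, periostin, from 2311 ± 83.4 to 1717 ± 64.6 FPKM (-0.39 ± 0.06, edgeR adjusted p = 0.00349). Other matrix genes did not pass, with Lum at 0.14 ± 0.06 (edgeR adjusted p = 0.256), Dcn at -0.12 ± 0.06 (edgeR adjusted p = 0.376) and Col3a1 at 0.10 ± 0.07 (edgeR adjusted p = 0.475), while Sparc stood at 0.30 ± 0.06 (edgeR adjusted p = 0.0182, and up to 0.106 without control replicate 2 or 3 or scaffold replicate 2 or 3, each of which ended its call). Apod, Fstl1 and Gas6 stood at -0.56 ± 0.08 (edgeR adjusted p = 0.00276), -0.46 ± 0.05 (edgeR adjusted p = 0.00129) and -0.37 ± 0.06 (edgeR adjusted p = 0.00376). The iron uptake genes Tfrc, the transferrin receptor, and Scara5, a ferritin receptor, stood at -0.72 ± 0.06 (edgeR adjusted p = 0.000247) and -0.62 ± 0.06 (edgeR adjusted p = 0.000459). Among GO terms of the lower genes, 2 passed Fisher's exact test: extracellular space (23 of 489, adjusted p = 0.0269) and collagen-containing extracellular matrix (12 of 173, adjusted p = 0.0469). The second also passed for the higher genes (20 of 173, adjusted p = 9.88e-05).

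Kidney transcripts were lower and heart transcripts higher in the scaffold libraries, at summed levels of 30.4 ± 2.80 against 12.1 ± 1.84 CPM for a kidney list and 8.23 ± 4.90 against 26.4 ± 2.50 CPM for a heart list. Depth or shallow detection of low transcripts would move other genes at the same level alike, and the tables argue against it. The members that the naming rule had not picked had median log2 ratios of -0.82 for kidney and 1.18 for heart. The medians of 1000 random sets of other genes matched to them in level ran from -0.53 to 0.34 for each list, so that both lists lay at least 0.29 beyond the farthest set. Trace RNA of other tissues, carried over at dissection or between samples, and a response of the sampled cells to the scaffold both stay open. Of the members that the naming rule had not picked, 100% had ratios in the direction of the named ones (14 of 14 lower for kidney, 17 of 17 higher for heart). Trace RNA needs this, but a joint response would give it as well. Singly, most of these members did not pass. With edgeR, 6 of 19 tested kidney genes were called lower, all of them named ones. Of 18 tested heart genes 4 were called higher, the 3 named ones and Fabp3. Some ratios rest on few counts, as for Actn2 with 32, 0 and 0 in control and 16, 26 and 20 in scaffold. Only 2 of 20 kidney and 3 of 20 heart members reach 1 FPKM, and 3 of the heart genes are also in the skeletal muscle list. The leading genes Kap and Myh6 stood at 9.48 and 0.475 CPM in control and 2.56 and 5.14 in scaffold. The heart sum in control replicate 1 (13.9 CPM) was 2.57 times the mean of the other control libraries, but below the lowest scaffold library (24.7 CPM). Without the genes picked by the naming rule, 13 tested kidney and 15 tested heart genes passed camera at the preset correlation (p = 9.52e-06 and 1.14e-08) but not with an estimated one (p = 0.0818 and 0.103), and the neuron list did not pass (p = 0.817, 1 of 7 tested genes lower), while with edgeR 0 of the 2 tested liver genes and 0 of the 4 tested blood genes were called (1 lower and 0 at an unadjusted p under 0.05). DESeq2 gave an adjusted p for 1 of these liver and 2 of these blood genes and limma tested 0 and 1, so their counts of 0 add little.

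The rise of a Septin2 gene model may reflect how reads were divided between overlapping models. Septin2, a cytoskeletal GTPase gene, has 2 models in the table, and the counts of ENSMUSG00000116048 rose while those of ENSMUSG00000026276 fell from 298 ± 12.2 to 178 ± 33.2 CPM. With both added, the level was 341 ± 7.10 CPM in control and 370 ± 10.8 in scaffold, a log2 fold change of 0.12 ± 0.05 (edgeR adjusted p = 0.258). More Septin2 RNA as the whole cause is excluded, since the added change plus 2 SE reaches only 0.22, against 2.16 for the rising model. A switch between transcripts of the locus would give the same division and was not tested.

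The joint rise of the mitosis, cholesterol, hypoxia and osteoblast lists was weighed against 2 technical explanations. A trend with GC content and gene length as the whole cause is argued against: after its removal from each library, each of the 4 lists passed the set test at the preset correlation and kept at least 90.7% of its median log2 fold change. That 1 library decides the lists is argued against as well, since without any 1 library each list passed at the preset correlation and kept at least 86.7% of its median, the lowest being hypoxia without control replicate 2. With an estimated correlation and all 6 libraries, the mitosis and osteoblast lists do not pass (adjusted p = 0.0596 each). The metformin, the carrier material, and a difference in cell density or tissue sampled between the groups stay open as untested explanations, because the design holds 1 treated group and the labels do not describe the control.

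The 6 libraries can be split into groups of 3 in 10 ways, which is too few for a share under 0.05. For genes past the threshold, 1 of the 10 splits, the real one, gave as many as 749, and the highest other gave 1. For lists past the set test, 1 of the 10, again the real one, gave as many as 16, and the highest other gave 13. Every other split mixes control and scaffold libraries on each side. A real difference then adds to the spread within each side and part of it remains between them. The counts of the other splits are therefore no reference for chance.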
